A study of Mus musculus with 3 samples.

How the data were processed

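RNA sequencing was done on 3 mouse liver samples, which the labels describe as healthy, wild-type, male and C57BL/6 (an inbred laboratory strain). Per the labels' protocols, total RNA with an RNA integrity number above 6.5 was taken into library preparation, and the text allows for either poly(A) selection or removal of ribosomal RNA without saying which was used. The submitters' processing notes name cutadapt 1.9.1, HISAT2 2.0.1, HTSeq 0.6.1, DESeq2 and the genome build mm9, without giving the role of each. The tool that made the tables used here is not given in the sources used here. The series also concerns liver cancers, and tumour samples were not analysed here.

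Each library came as 1 table of transcript-structure events: first exons, last exons, skipped exons, retained introns and alternative exon ends, each with a position and a value. The value is an FPKM (fragments scaled to transcript length and library size) computed by the authors, per the file headers, and it is the sum over the assembled transcripts that carry the event. Events at 0 are not listed, the lowest listed FPKM was 1e-06, and the tables hold no read counts, so the depth of each library is unknown and no counting interval was given. Between 1440 and 1519 identical rows per library were removed, which left 71716, 74243 and 74236 events in replicates 1, 2 and 3.

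The build was checked against GENCODE M21, an annotation of GRCm38. Of the first exons in the 3 libraries, 82.0%, 82.3% and 82.7% had exactly the position and strand of an annotated first exon, and at most 0.00564% did after a shift of 1000 bases. The positions were therefore read as GRCm38, although the processing notes name mm9. First and last exons were given to a gene by exact position, then by splice site, then by the gene identifier in the table; at most 1.65% could not be placed.

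Gene-level FPKM was computed for each library as the largest of 3 sums or values: the sum over the gene's first exons, the sum over its last exons, and its largest internal event where the locus held 1 gene. Each is part of the gene's expression as far as its events belong to the gene, and the result is then a lower bound. The 5.51, 5.11 and 4.54% of ends placed by identifier in replicates 1, 2 and 3 were not checked for strand or position. Some may belong to other transcripts, such as a plus-strand first exon of 2.23 FPKM in replicate 1 counted for the minus-strand gene Fn1. This definition was chosen after the values had been seen, because the first or last exon of a main transcript was sometimes absent from a table. It gave a value for 13167 genes, 12106 of them protein-coding. Protein-coding genes with several annotated transcripts had a value in 64.1% of cases, and those with 1 annotated transcript in 19.9%, so the absence of a gene from the tables is not evidence that it was silent. Gapdh, a gene used by all cells, had values of 0, 0 and 6.53 FPKM. For genes with a value of 0 in any library the single values are therefore given instead of a mean and SD.

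All 3 libraries belong to 1 group, so no contrast between groups could be made. The design for the spread between libraries had assumed counts; since none were given, its written fallback was used. The residual variance of log2(FPKM + 1) was compared with its trend over mean expression in limma 3.58.1 under R 4.3.3, for the 9615 genes with a mean of at least 1 FPKM, with a robust prior, an upper-tail F test and Benjamini-Hochberg adjustment at 0.05. In simulated data for this comparison, run on 9615 genes with 200 of them given a larger SD, the test recovered 0% of genes with an 8-fold larger SD when the prior had 3 or 4 degrees of freedom, and 67% when it had 10. The fitted prior had 3.41 degrees of freedom; in 10 simulations at that prior, added after the data were seen, 0% were recovered, so the test could not be expected to call genes.

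Before the data were examined, 45 gene lists and 20 gene pairs had been fixed, with these results to be computed: the level of each list, as the median over members of mean log2(FPKM + 1) with its percentile among 10000 random lists of genes with a mean of at least 1 FPKM; the deviation of each list in each library from the members' means, and the spread of each list, both with percentiles among 10000 random lists matched on mean expression and only for lists with at least 5 members; and the log2 difference within each pair. Random lists of genes with a mean of at least 1 FPKM cannot hold genes under it, so a list with many members under 1 FPKM falls below them by construction. For list medians that include members under 1 FPKM, and are not above all random lists, the percentile among random lists of all genes with a value is therefore given; this setting was fixed beforehand as an alternative, and its use in the text was chosen after the values had been seen. Percentiles describe these libraries and are not tests, and members of a list that are regulated together make extreme percentiles more frequent. In 100 simulations over 9615 genes, a list of 10 genes moved by 1 log2 unit in 1 library was found 100 times, and an unmoved list fell outside the central 95% in 8. The simulated genes had independent normal noise with the same SD for all, the median SD of the real genes. These rates therefore need not hold for the real lists.

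The genes named in the text follow a rule fixed at the same time: the 10 genes with the highest mean FPKM; in each list up to 4 members with the highest mean, any member that passed the spread test, and members with a mean under 1 FPKM; Xist and Y-linked genes as a check of the labelled sex; up to 25 genes with the largest SD among those that passed the spread test, of which there were none; and the gene pairs. Some genes and pairs that this rule selects are not reported here. Members under 1 FPKM were given as counts with examples where there were many, and the X-linked counterparts of the Y-linked genes were added after the values had been seen. Gene ontology was not tested, since no gene passed. Inclusion levels of exons and introns, and the use of first exons, were computed as additional results after the kind of table was known, for 40 genes chosen before their event values were seen, apart from example rows of Alb and Apoa1. Alternatives covered the pseudocount, the expression minimum, the prior, each replicate left out, scaling and the definition of the gene value. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used for the other steps.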

Results

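Gene expression was measured by RNA sequencing in 3 libraries of normal mouse liver, labelled wild type, healthy, male and C57BL/6 and numbered as replicates 1 to 3. The series is about driver genes and signalling pathways in hepatocellular carcinoma, the main cancer of hepatocytes, and these libraries form its normal liver group. Tumours were not analysed here, so the questions that the libraries could answer were which genes normal liver expressed and how far the 3 libraries differed. The labels do not say whether the replicates came from separate animals, so the spread given below may be technical in part. Values are FPKM at gene level, given as mean ± SD over n = 3 libraries, and positions are on GRCm38.

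A mean of at least 1 FPKM was reached by 9615 genes, with 9537, 9514 and 9522 genes at that level in replicates 1, 2 and 3, and 8634 genes in each of them. Across these 9615 genes, which are not independent replicates, Pearson's r of log2(FPKM + 1) was 0.944 between replicates 1 and 2, 0.950 between 1 and 3 and 0.957 between 2 and 3. Spearman's rho was 0.923, 0.928 and 0.939 for the same pairs. The 10 most abundant genes made up 21.4% ± 1.77 of the summed FPKM (SD, n = 3).

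Secreted plasma proteins dominated the libraries. Albumin (Alb, ENSMUSG00000029368, chromosome 5, 90460897 to 90476602, plus strand) was at 27659 ± 2671 FPKM. It was followed by the lipoprotein components Apoa2 at 9704 ± 3897 FPKM, Apoe at 5128 ± 2363 FPKM and Apoc1 at 4280 ± 833 FPKM, and by the fatty acid binding protein Fabp1 at 6484 ± 1159 FPKM. The carriers Ahsg, Trf, Ttr, Selenop and Gc completed the 10 most abundant genes, with means between 2957 and 4039 FPKM. Selenop, the selenium carrier, at 2994 ± 59.3 FPKM and the vitamin D binding protein Gc at 2957 ± 64.1 FPKM had the smallest relative spread of the 10, with coefficients of variation of 1.98% and 2.17%, against 46.1% for Apoe. All 25 plasma protein genes had a mean of at least 1 FPKM, and their median log2(FPKM + 1) of 11.01 lay above all 10000 random lists. Serpina1a and Serpina1b are near-identical copies, and their separate values are uncertain.

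Genes of hepatocyte metabolism were high as groups. The 9 urea cycle and ammonia genes had a median of 7.33 on the log2(FPKM + 1) scale, led by Ass1 at 569 ± 62.5 FPKM, Glul at 352 ± 54.3 FPKM, Arg1 at 352 ± 38.2 FPKM and Cps1 at 266 ± 96.1 FPKM. The 16 drug metabolism genes had a median of 7.20, with Cyp2e1 at 2231 ± 375 FPKM, Gstm1 at 885 ± 315 FPKM and Cyp3a11 at 805 ± 79.0 FPKM. For bile acid synthesis and transport, 11 of 12 genes had a value and a median of 6.84, with the acid ligase Slc27a5 at 255 ± 38.1 FPKM and the uptake carrier Slc10a1 at 229 ± 50.2 FPKM. The 10 glucose and glycogen genes had a median of 6.29, with Pck1, the gluconeogenic carboxykinase, at 559 ± 214 FPKM and Fbp1 at 374 ± 25.3 FPKM. The 17 fatty acid oxidation genes had a median of 6.17. All 5 of these lists lay above all random lists. Lipogenesis, with 9 of 10 genes measured, had a median of 5.13 at the 99.8th percentile, and the 12 cholesterol synthesis genes had a median of 4.65 at the 99.7th, with Insig1 at 116 ± 32.4 FPKM and Hmgcs1 at 115 ± 5.19 FPKM.

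**Figure D1:**
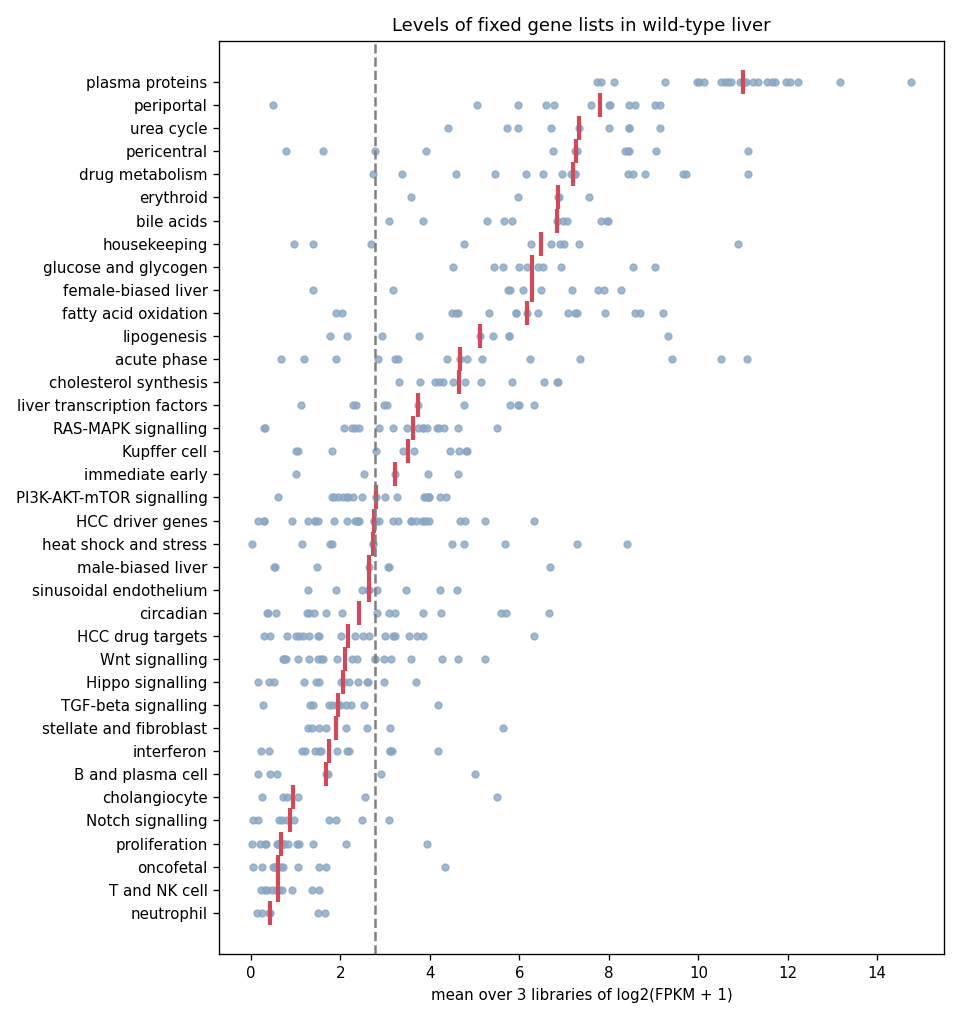
Levels of the gene lists with at least 5 measured members. Each point is 1 gene at its mean log2(FPKM + 1) over the 3 libraries, red bars are list medians, and the dashed line is the median of genes with a mean of at least 1 FPKM (2.77); plasma proteins sit highest at a median of 11.01 and neutrophil genes lowest at 0.42.

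Both ends of the liver lobule were represented. Pericentral genes, expressed around the central vein, had a median of 7.27, and beside Cyp2e1 and Glul they included Rgn at 533 ± 59.8 FPKM and Cyp2a5 at 364 ± 130 FPKM. The Wnt receptor partner Lgr5 was the only one of 12 under 1 FPKM, at 0.75 ± 0.43. Periportal genes had a median of 7.80, with Pigr at 386 ± 77.6 FPKM beside Ass1, Pck1 and Arg1; the cadherin Cdh1 had values of 0, 1.83 and 0 FPKM. Both lists lay above all random lists. Of 14 liver transcription factors, 11 had a value and a median of 3.74 at the 93.8th percentile of random lists of genes at 1 FPKM or more and the 98.6th of random lists of all genes with a value, led by Hnf4a at 81.0 ± 19.5 FPKM, Rxra at 63.3 ± 10.7 FPKM, Xbp1 at 62.0 ± 8.19 FPKM and Creb3l3 at 55.5 ± 15.1 FPKM. Foxa3, Cebpa and Cebpb were not listed.

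Most genes altered in human hepatocellular carcinoma were expressed in these normal libraries. Of 32 such genes 31 had a value, 28 had a mean of at least 1 FPKM, and the median of 2.76 lay at the 48.3rd percentile of random lists of genes at that minimum and at the 93.7th of random lists of all genes with a value. The highest were the angiogenic factor Vegfa at 79.7 ± 15.6 FPKM, beta-catenin (Ctnnb1) at 36.7 ± 4.92 FPKM, cyclin D1 (Ccnd1) at 26.9 ± 4.05 FPKM and the oxidative stress regulator Nfe2l2 at 24.6 ± 1.92 FPKM. Low values were found for Braf (0, 0 and 0.82 FPKM), Arid2 (0, 0.28 and 0.47 FPKM) and the tumour suppressor Cdkn2a (0.42, 0 and 0 FPKM), and Fgf15 was not listed. Of 23 targets of drugs used or tested in this cancer, 20 had a value with a median of 2.17 at the 57.7th percentile of random lists of all genes with a value. Beside Vegfa, the high ones included Cdk4 at 12.5 ± 4.56 FPKM and the receptor Fgfr4 at 10.6 ± 0.49 FPKM. Kit, a receptor kinase, was at 0.84 ± 0.65 FPKM, Flt1 had values of 0, 0.45 and 0.70 FPKM, and Ret, Pdcd1 and Ctla4 were not listed.

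Of the signalling lists, RAS-MAPK, with 18 of 23 genes measured, had the highest median at 3.61, at the 96.2nd percentile of random lists of genes at 1 FPKM or more and the 99.5th of random lists of all genes with a value; it was led by Map2k2 at 44.6 ± 7.61 FPKM, Dusp6 at 27.5 ± 15.4 FPKM, Erbb3 at 19.2 ± 3.13 FPKM and Mapk3 at 17.5 ± 3.30 FPKM. The PI3K-AKT-mTOR list followed with a median of 2.80, at the 89.3rd percentile among all genes with a value, with Gsk3a at 19.6 ± 2.10 FPKM, Rheb at 17.8 ± 1.17 FPKM and Akt2 at 15.4 ± 4.54 FPKM. Wnt genes had a median of 2.09 at the 50.55th percentile, among them the secreted Wnt inhibitor Notum at 18.4 ± 0.99 FPKM and the ligand Wnt2 at 0.66 ± 0.083 FPKM. Hippo genes had a median of 2.05 at the 48.0th percentile, led by the coactivator Yap1 at 12.1 ± 2.63 FPKM. TGF-beta genes had a median of 1.94 at the 41.2nd percentile, led by Id1 at 17.4 ± 2.91 FPKM. Notch genes had a median of 0.88 at the 3.99th percentile, with Hes1 highest at 7.64 ± 2.18 FPKM and 4 of 10 measured genes at 1 FPKM or more. The medians of the 5 lists other than RAS-MAPK lay inside the central 95% of random lists of all genes with a value, and no test compared the lists with each other.

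Genes of fetal liver, liver tumours and cell division were low. For the 18 oncofetal genes, 12 had a value and 4 reached 1 FPKM, and the median of 0.61 lay at the 0.65th percentile of random lists of all genes with a value. Alpha-fetoprotein (Afp) had values of 1.52, 0 and 0.12 FPKM, glypican 3 (Gpc3) was at 0.46 ± 0.13 FPKM and the noncoding RNA H19 at 0.19 ± 0.12 FPKM, while Igf2, Lin28b and Sall4 were not listed. The exception was Ly6d, with 62.5, 6.48 and 16.6 FPKM in replicates 1, 2 and 3. Of 21 proliferation genes 19 had a value and 5 reached 1 FPKM, with a median of 0.68 at the 0.24th percentile of the same lists. The replication clamp Pcna was at 14.3 ± 1.18 FPKM, whereas Mki67 was at 0.52 ± 0.14 FPKM and Top2a at 0.64 ± 0.45 FPKM.

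Pairs of related genes showed the liver forms in excess. Of 20 pairs, 19 could be computed, and the first gene was the higher one in all 3 libraries in 14. The glucose carrier Slc2a2 exceeded Slc2a1 by 5.27 ± 0.22 on the log2(FPKM + 1) scale, Gys2 exceeded Gys1 by 4.77 ± 0.41, Mat1a exceeded Mat2a by 4.76 ± 0.22 and Pklr exceeded Pkm by 3.16 ± 0.49. Ldha exceeded Ldhb by 7.06 ± 0.14, Cyp2e1 exceeded Cyp2f2 by 3.07 ± 0.034 and Fgfr4 exceeded Fgfr1 by 2.53 ± 0.072. Differences were close to their SD or smaller for Akt2 and Akt1 (0.13 ± 0.38) and for Stk3 and Stk4 (-0.50 ± 0.37). Afp and Pygm, the second genes of 2 more pairs with a higher first gene, had no listed value in at least 1 library. These differences are given as values, and no test of them was made. The size of several differences depended on the gene value: for Slc2a2 and Slc2a1 it was 3.27 with first exons alone, and for Pklr and Pkm 5.71 with last exons alone. With last exons alone, the differences for Ldha and Ldhb and for Cyp2e1 and Cyp2f2 changed sign, to -0.51 and -8.04. The -8.04 is the mean Cyp2f2 level with a minus sign. Cyp2e1 had no last exon value in any library, so its excess was not measured under that setting.

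Other cell types were seen at graded levels. Kupffer cell genes, from the resident macrophages, were all at 1 FPKM or more with a median of 3.52, led by Cd5l at 28.6 ± 9.71 FPKM, C1qa at 27.1 ± 2.51 FPKM, C1qb at 24.4 ± 3.32 FPKM and Clec4f at 21.3 ± 5.95 FPKM. The 9 genes of sinusoidal endothelium had a median of 2.63, with Clec4g at 23.5 ± 3.64 FPKM and Fcgr2b at 17.6 ± 0.51 FPKM. Stellate cell and fibroblast genes had a median of 1.91, with Ecm1 at 49.1 ± 7.38 FPKM and Rgs5 at 7.91 ± 2.33 FPKM. B and plasma cell genes had a median of 1.67, at the 31.7th percentile of random lists of all genes with a value, with Ighm at 32.3 ± 9.03 FPKM. Cholangiocyte genes had a median of 0.93 at the 8.04th percentile, with Spp1 at 47.5 ± 24.4 FPKM and Krt19 at 0.67 ± 0.29 FPKM. T and NK cell genes, with Nkg7 at 1.898 ± 0.54 FPKM, and neutrophil genes, with S100a8 at 1.85 ± 0.40 FPKM, had medians of 0.60 and 0.42, at the 0.92nd and 1.09th percentiles. Of the acinar pancreas genes 1 of 7 had a value, Cela1 at 8.32 ± 0.98 FPKM, of the adipocyte genes 1 of 5, Cfd with 0.73, 0 and 0 FPKM, and of the mesothelium genes 2 of 4, Krt8 at 107 ± 42.0 FPKM, which hepatocytes also express, and Upk3b at 0.36 ± 0.17 FPKM.

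Among inflammatory and stress groups, 15 of 17 acute phase genes had a value and a median of 4.67 at the 99.9th percentile. The iron hormone Hamp was at 2295 ± 833 FPKM, haptoglobin (Hp) at 1479 ± 343 FPKM, Orm1 at 681 ± 20.6 FPKM and Crp at 164 ± 16.4 FPKM. Interferon genes had a median of 1.74 at the 29.0th percentile of random lists of all genes with a value, led by Irf7 at 17.4 ± 3.26 FPKM and Ifit3 at 7.93 ± 1.22 FPKM. Heat shock and stress genes had a median of 2.73 at the 81.1st percentile of the same lists, with Hspa8 at 339 ± 44.0 FPKM and Hspa5 at 157 ± 21.8 FPKM. The 10 housekeeping genes had a median of 6.48, with B2m at 1893 ± 153 FPKM and Actb at 130 ± 40.5 FPKM. None of 15 mitochondrial genes were listed. Of the 11 genes fixed beforehand as RNAs without a poly(A) tail 1 was listed, the histone gene Hist1h2bc at 127 ± 25.8 FPKM. Whether its RNA carried a tail was not measured. Of the major urinary protein genes, which are near-identical copies with uncertain values, 4 of 13 were listed, with Mup3 at 1402 ± 328 FPKM.

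Sex-linked genes did not match the label in any of the 3 libraries labelled male. Xist, the noncoding RNA that silences an X chromosome in female cells (ENSMUSG00000086503, chromosome X, 103460366 to 103483254, minus strand), was at 39.6, 34.2 and 38.2 FPKM in replicates 1, 2 and 3, with all listed events on its own strand and none on that of its antisense partner Tsix. No event was listed inside the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y. These have 4, 12, 9 and 6 annotated transcripts, and their X-linked counterparts Ddx3x, Kdm6a, Kdm5c and Eif2s3x were at 36.0 ± 5.74, 2.02 ± 0.34, 8.76 ± 1.00 and 30.1 ± 6.78 FPKM. The Y chromosome had 8, 8 and 7 listed events, all between positions 90738977 and 90822377, far from these genes.

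Sex-biased genes of liver were also measured in the libraries labelled male. All 10 genes known to be higher in female liver had a mean of at least 1 FPKM and a median of 6.29 on the log2(FPKM + 1) scale, above 99.99% of random lists. They were led by A1bg at 344 ± 190 FPKM, Cyp2c69 at 244 ± 149 FPKM, Sult2a1 at 237 ± 38.3 FPKM and Cyp3a41a at 207 ± 217 FPKM. Of 10 genes known to be higher in male liver 7 had a value, 5 reached 1 FPKM, and the median was 2.64, inside the central 95% of random lists at the 71.7th percentile among all genes with a value. Mup20 was at 127 ± 109 FPKM, Cyp2d9 at 8.63 ± 6.00 FPKM, Cyp4a12a at 7.80 ± 7.27 FPKM and Cyp7b1 at 7.70 ± 2.15 FPKM, the carrier Slco1a1 had values of 0.94, 0.58 and 0 FPKM, and Hsd3b5 was not listed. No test compared the lists, and the libraries differed on both, with replicate 1 lower on the female-biased and higher on the male-biased genes (medians of -0.82 and 0.94 log2 units from the members' means). Many of these genes, the Cyp and Sult genes and Mup20 among them, have close paralogs that could share reads, so their separate values are uncertain.

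**Figure D2:**
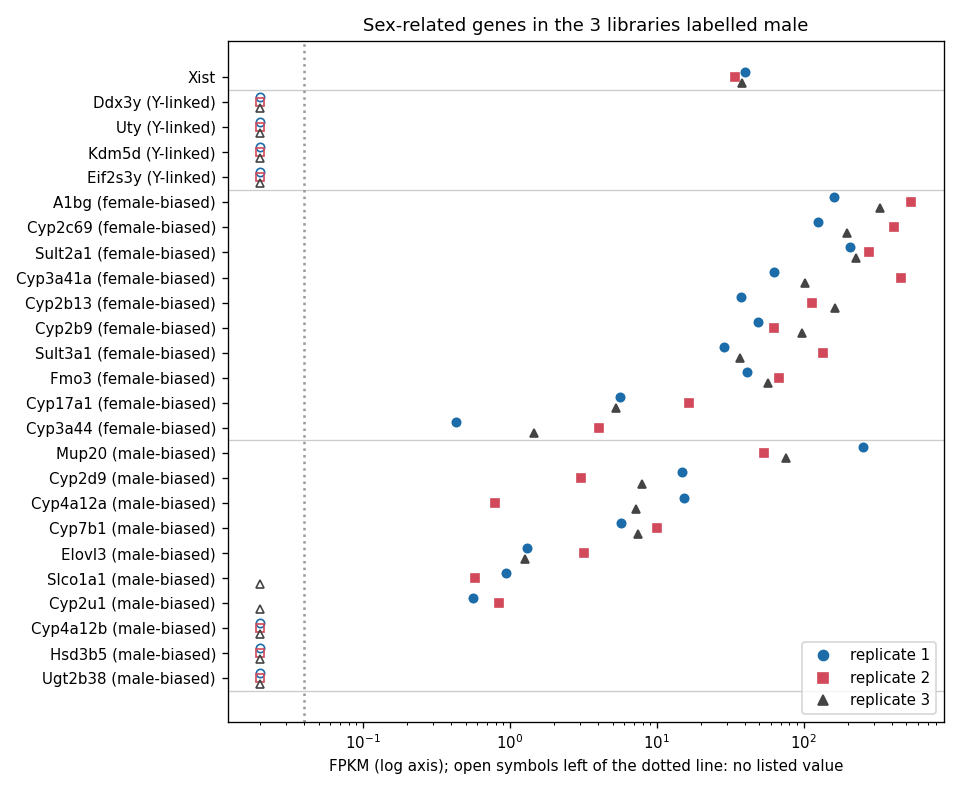
FPKM on a log axis of Xist, Y-linked genes and genes known to be higher in female or male liver, with 1 symbol per replicate and open symbols left of the dotted line for genes with no listed value. Xist sits between 34.2 and 39.6 FPKM in the 3 libraries labelled male, and none of the 4 Y-linked genes has a value.

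The spread of each gene between the 3 libraries was compared with that of genes of like abundance. limma's test of spread called 0 of 9615 genes after Benjamini-Hochberg adjustment, and 525 had an unadjusted p under 0.05. A share of 0.05 of the genes would fall under that threshold by chance if the fitted prior held, so the 525 are not read as variable genes. In 10 simulations with the prior fitted here the test recovered no gene, so the count of 0 does not show that the libraries were alike.

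As groups, 10 of 31 lists had a median spread above the central 95% of random lists, against 1.55 lists expected outside it by chance. These were lipogenesis, female-biased, male-biased, immediate early, erythroid, circadian, fatty acid oxidation, Kupffer cell, liver transcription factor and glucose and glycogen genes. Without replicate 2, 3 of these 10 stayed above it: Kupffer cell, male-biased and female-biased genes. The spread of PI3K-AKT-mTOR, RAS-MAPK and HCC driver genes lay at the 4.04th, 14.7th and 42.6th percentiles.

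Of 93 list medians by library, 31 lay outside the central 95% of random lists matched on expression, against 4.65 expected by chance, with 7 above and 7 below it in replicate 2, 3 above and 8 below in replicate 1, and 4 above and 2 below in replicate 3. Lipogenic genes were low in replicate 2, with a median deviation of -0.75 log2 units against 0.58 and 0.15 in replicates 1 and 3, and with all 9 genes below their means: Fasn, the fatty acid synthase, had 62.5, 21.3 and 53.03 FPKM in replicates 1, 2 and 3, Scd1 had 856, 432 and 711 FPKM, Srebf1 had 85.9, 40.2 and 44.0 FPKM and Me1 had 66.3, 43.7 and 51.9 FPKM. All 10 glucose and glycogen genes were also below their means, with a median of -0.36 and 728, 318 and 630 FPKM for Pck1. Fatty acid oxidation genes lay higher there, at 0.35 against -0.28 and -0.044, with 369, 904 and 627 FPKM for Cyp4a14 and 271, 593 and 443 FPKM for Cyp4a10, which are close paralogs. Immediate early genes, with 5 of 11 measured, lay at -1.16 against 0.93 and 0.52, with 33.6, 3.51 and 22.8 FPKM for Dusp1, 25.8, 0.76 and 15.8 FPKM for Nr4a1 and 10.03, 1.58 and 5.75 FPKM for Fos, but 18.3, 36.0 and 19.9 FPKM for Egr1. Circadian genes lay at -0.31 against 0.12 and 0.14, but at -0.044, inside the central range, with last exons alone, with 130, 69.4 and 110 FPKM for Dbp and 58.8, 30.2 and 59.1 FPKM for Tef, and with 51.5 ± 5.41 FPKM for Nr1d1.

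Red cell genes also stood apart in replicate 2, with a median deviation of 1.01 against -0.38 and -0.61 in replicates 1 and 3. Hbb-bs had 142, 425 and 110 FPKM, Hba-a1 had 90.6, 231 and 78.7 FPKM, Hba-a2 had 87.5, 233 and 75.0 FPKM and Hbb-bt had 50.1, 135 and 34.5 FPKM. The alpha genes are near-identical copies and so are the beta genes, and their separate values are uncertain. Alas2, the haem synthesis enzyme of red cell precursors and the remaining listed member, was at 11.0 ± 1.17 FPKM. Female-biased genes lay at 0.87 in replicate 2 and -0.82 in replicate 1, and male-biased genes at -0.90 and 0.94. The male-biased medians rest on 5 genes, of which Cyp7b1 and Elovl3, the latter named after its values were seen, went the other way in both libraries. Kupffer cell genes lay at -0.34 in replicate 1, but at -0.21 and inside the central range with a minimum of 5 FPKM, and at 0.33 in replicate 2, with 17.4, 34.2 and 34.2 FPKM for Cd5l. The other lists with a median outside the central range in some library were bile acid, drug metabolism, pericentral, periportal, cholesterol synthesis, interferon, stellate and fibroblast, and liver transcription factor genes, and those medians lay between -0.25 and 0.18; 8 of these 12 medians fell inside the range under at least 1 alternative setting.

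**Figure D3:**
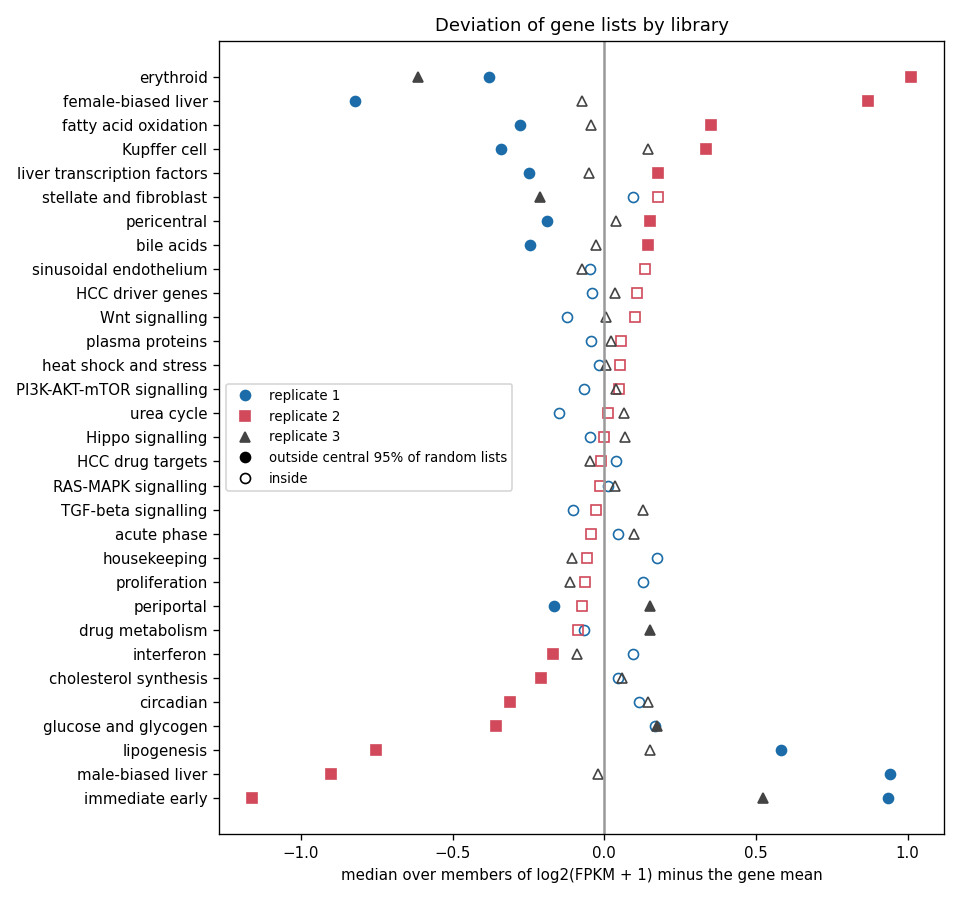
Median over list members of log2(FPKM + 1) minus the gene's mean over the 3 libraries, for 31 lists, with 1 symbol per replicate; filled symbols lie outside the central 95% of matched random lists. In replicate 2, immediate early (-1.16) and lipogenesis (-0.75) genes lie on the low side and erythroid (1.01) genes on the high side.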

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

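The spread test called 0 genes under each of the 12 other settings tried, among them 5 chosen after the data were seen, and it could not be expected to call genes at this prior. The number of genes at the expression minimum was 9615, 12613 with a minimum of 0.1 FPKM and 5335 with 5 FPKM. It was between 7204 and 9471 with the gene values chosen after the data were seen (first exons only, last exons only, either of them fixed per gene, or the files' own gene identifiers), and between 9535 and 9581 with 1 replicate left out. Mean Pearson's r between libraries was 0.950; it was 0.910 with a pseudocount of 0.1, 0.961 with no filter, 0.924 with first exons only and 0.961 for genes with a value in all 3 libraries, and between 0.944 and 0.957 with 1 replicate left out. The share of the 10 most abundant genes was 21.4%, and 26.6% with last exons only; the cause was not tested. The number of lists with a level outside the central 95% was 22 and ranged from 20 to 27, and no list moved from one side to the other. With random lists of all genes with a value, 6 lists changed: liver transcription factors and RAS-MAPK came to lie above the central 95%, and interferon, cholangiocyte, Notch and adipocyte genes no longer lay below it; first exons only changed 9 lists and the other alternatives at most 4. The number of list medians by library outside it was 31, and 20 with a minimum of 5 FPKM, under which fewer lists had 5 members (72 medians against 93). Elsewhere it lay between 26 and 32, and no median outside the central range moved to the other side of it under any alternative; 10 of the 31 were inside the range under at least 1 alternative. With last exons only, the circadian median in replicate 2 went from -0.31 to -0.044, periportal genes in replicate 1 from -0.17 to -0.0019 and drug metabolism genes in replicate 3 from 0.15 to 0.065, and with first exons only, stellate and fibroblast genes in replicate 3 from -0.21 to -0.025; the others were pericentral genes in replicates 1 and 2, periportal genes in replicate 3, Kupffer cell genes in replicate 1, and interferon and liver transcription factor genes in replicate 2. The number of lists with a spread outside it was 10, and between 4 and 9 with 1 replicate left out, lowest without replicate 2; this alternative was added after the data were seen. The first gene was the higher one in all libraries in 14 pairs, and in 10 to 16 under the alternatives. Of 11 pairs reported here, the difference moved by more than 1 SD in 6 with a pseudocount of 0.1, all to larger values, in 2 with first exons only and in 3 with last exons only, apart from 2 that changed sign; Slc2a2 and Slc2a1 went from 5.27 to 3.27 with first exons only, and with last exons only Pklr and Pkm went from 3.16 to 5.71, Pygl and Pygm from 6.46 to 0.82 and Fgfr4 and Fgfr1 from 2.53 to 3.52. With last exons only, an alternative chosen after the data were seen, the log2 differences became -0.51 for Ldha and Ldhb and -8.04 for Cyp2e1 and Cyp2f2. Cyp2e1 had no last exon value in any library, so its sign change reflects unlisted rows. The cause for Ldha and Ldhb was not tested. Of 434 genes selected for naming and reported here, the mean FPKM moved by more than 1 SD in 89 with first exons only and in 93 with last exons only. Settings fixed beforehand that needed counts (the other unit for the share of the top genes, size factors and upper quartile scaling) were not run, since no counts were given. No paired analysis was possible because all 3 libraries belong to 1 group. List deviations were not recomputed with a replicate left out, since the deviations of the remaining pair are mirror images. Without counts, the precision set by sequencing depth is unknown for every value.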

Other observations

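The tables also gave exon inclusion and first exon use, computed after the kind of table was known and under 1 setting. There were 3674 exon skipping events over 2552 genes with FPKM for both forms summing to at least 1, and the same exon can occur in several events. Inclusion differed by less than 10 percentage points between the libraries for 45.5% of events. Pearson's r across events was between 0.804 and 0.822. In Insr, the insulin receptor, the exon at chromosome 8, 3181702 to 3181737 (36 bases, minus strand) was included at 98.8% ± 2.16 (SD, n = 3). In the fibronectin gene Fn1, the exon of 270 bases at chromosome 1, 71603660 to 71603929 was included at 0, 0.0022 and 0%. In Csnk1d, a kinase of the clock, an exon of 63 bases was included at 77.8% ± 0.15, and in Igf1 an exon of 52 bases at chromosome 10, 87915298 to 87915349 at 39.9% ± 3.56. In Yap1, the exon of 48 bases at chromosome 9, 7950492 to 7950539 varied between libraries, at 31.1, 56.4 and 70.7%.

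Of 4628 genes with 2 or more first exons, 76.6% had a main first exon with the same lower coordinate in all 3 libraries. First exons that share this coordinate but end elsewhere counted as the same. For Pklr, the exon from 89136572 to 89136618 on chromosome 3 carried 35.5, 17.6 and 100% in replicates 1, 2 and 3. The longer one, to 89137406, carried 64.5, 82.4 and 0%. For Hnf4a, the first exon at chromosome 2, 163547187 to 163547419 carried 99.7% ± 0.29 of the first exon FPKM, and for Srebf1 the downstream one at chromosome 11, 60210336 to 60210465 carried 80.5% ± 11.1. Such shares cover listed first exons only. The downstream Srebf1 exon had 42.3, 23.9 and 13.2 FPKM in replicates 1, 2 and 3, and the upstream one 8.59, 2.64 and 5.58 FPKM. The gene values of Srebf1 were higher, at 85.9, 40.2 and 44.0 FPKM. Intron retention had a median inclusion of 9.42, 5.58 and 4.62% in replicates 1, 2 and 3, over 2627 events. The same intron can occur in several of these events.

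Of the tests below, those of a female-type liver in male animals and of a longer fast were chosen only after the values they rest on had been seen. In all 3 libraries labelled male, Xist was present and the 4 Y-linked genes were not listed. A female-type expression of autosomal genes in male animals is argued against by Xist, whose lowest value was 34.2 FPKM. A lack of Y-linked genes because genes with 1 annotated transcript are rarely listed is argued against by the annotation, in which 4 of the 4 genes have 2 or more transcripts. Female animals are consistent with Cux2, a transcription factor of female liver that had not been examined before, at 1.97 FPKM or more in each library. That the livers came from female mice stays a candidate explanation. Rows absent from the tables for other reasons stay open for the Y-linked genes alone. Absent rows could not give Xist at 34.2 FPKM or more in each library, so Xist argues against them as the whole cause.

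Replicate 2 stood apart in lipogenic, fatty acid oxidation and clock genes, with replicate 1 at the opposite end for lipogenic and fatty acid oxidation genes. Its largest median deviations were those of immediate early genes (-1.16) and red cell genes (1.01), for which no explanation was tested. For the lipogenic genes, members without a first or last exon value in some library are argued against as the whole cause. Members with such a value in all 3 libraries were still low in replicate 2. Their median deviation was -0.70 with first exons only and -0.59 with last exons only. The same medians, computed for the other lists after the data were seen, were 0.34 and 0.33 for fatty acid oxidation genes. For clock genes they were -0.25 and -0.044, so members without a value stay open there. A member with a value can still lack some of its rows, as for Srebf1, whose listed first exons fell short of its gene values. Rows left out in part therefore stay open for all of these lists. The fasting-induced genes Pck1, G6pc, Tat, Igfbp1 and Ppargc1a had a median deviation of -0.73, with Ppargc1a alone at -0.041. Tat and Igfbp1, which are not on the glucose list, lay at -0.78 and -0.88. Pck1 and G6pc had been seen to be low as members of that list before they were chosen. The genes moved opposite to a longer fast, but in 1 library only, so a longer fast stays open. Another time of day at collection is consistent with 3 other clock outputs, Usp2, Wee1 and Bhlhe41, with a median of -0.61, although Bhlhe41 alone lay at 0.11 and Nr1d1 at 0.14. This test was first computed without Bhlhe41, which lay under the expression minimum, with a median of -0.84, and was recomputed over all 3 genes after that value had been seen; the reading was the same both times. Time of day and other differences between the libraries stay open as hypotheses, since the labels give no collection time and the pattern rests on 1 library.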
